A study of Mus musculus with 6 samples.

How the data were processed

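Gene expression was measured by RNA sequencing in ovaries of balb/c-nude mice, an immunodeficient strain in which human tumor cells can grow. The labels name 3 control and 3 tumor-bearing samples, all taken on day 80, and each label carries a replicate number from 1 to 3. The tumor mice had received cells that the labels call MBA-MD-231, injected under the skin; the treatment labels count the last number of that name upward over the 3 tumor samples, while the cell line label stays the same. Per the labels' protocols, total RNA was extracted with Trizol and sequenced as single-end reads of 50 bases on an MGIseq500 instrument. How RNA species were selected, whether the library kept strand, and which animals or litters the samples came from are not given in the sources used here. The p-values therefore measure the spread between these samples, which were taken as separate animals only because the labels list them separately.

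Per the submitters' processing notes, HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and the genome build GRCm38.p6 were used, with no role or order stated. The authors deposited estimated counts per gene, of which 39.2% of the values above 0 were not whole numbers. The authors also deposited FPKM and TPM values for each library, per the file headers. A deposited table of the authors' own DESeq2 comparison gave log2 fold changes, p-values and q-values, per the file headers. Deposited TPM values entered no comparison. A further 30 columns of expression values were not used, since they repeat the gene values in the annotated table or give FPKM and TPM per transcript, and the group means in the files were not used either. The gene table held 19423 protein-coding genes and no gene of the mitochondrial chromosome. Estimated counts of the 65091 deposited transcripts summed to the gene count within 0.1 reads in all 6 libraries for 19399 genes. Gene positions came from the deposited annotation, and 100.0% of the 19263 genes matched by NCBI gene number overlapped their position in a GRCm38.p6 RefSeq table.

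Total estimated counts per library lay between 18278614 and 19238900. A count of 3, taken as the upper limit that a count of 0 allows, corresponds to between 0.156 and 0.164 CPM in these libraries. These CPM use the library's total without the TMM factors described below. Limits of this kind cover counting error only, because reads without molecular identifiers are not independent molecules. No 2 libraries agreed within sampling noise: the chi-square statistic per degree of freedom between any 2 libraries was at least 12.6, so all 6 were kept as separate samples.

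Estimated counts were rounded to whole numbers. Genes were kept by the filterByExpr function of edgeR 4.0.16 in R 4.3.3 with the group as its argument, which left 15787 genes. Libraries were scaled by TMM factors, which lay between 0.962 and 1.054. Tumor and control were compared with edgeR's quasi-likelihood F test with robust dispersion and group as the only term, followed by Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. Positive log2 fold changes mean higher in tumor. The standard error of a log2 fold change was taken as its absolute value divided by the square root of F. Levels are given as TMM-normalized CPM, counts scaled to the library's total, with mean and SD over 3 libraries. Before the data were examined, 31 gene lists were fixed, holding 510 genes of which 475 were tested; 30 lists had at least 5 tested genes. These were compared with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 30 lists. Camera with an estimated correlation and fry, a test of whether the genes of a list move on balance one way, were run beside it. Camera compares a list with all other genes, and with an estimated correlation no list passed the threshold.

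Named genes were chosen by a rule fixed before the data were examined. Its first part took the 10 genes higher and the 10 lower with the largest absolute log2 fold change among genes with adjusted p under 0.05, an average log2 CPM of at least 1 and no overlap between the 3 tumor and 3 control libraries, skipping predicted genes without a curated symbol. Its second part took up to 4 members with the smallest p from each list described. Its last part was a panel of ovarian, antioxidant, DNA damage and PI3K pathway genes, from which members were taken by topic whether or not they passed the test. The 18 genes named for their values outside this rule, all in the closing section, are marked there as chosen after their values were seen.

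The tests were tried on simulated data before use. Counts for the tested genes were drawn with the means and dispersions of the real tumor against control comparison, and 200 genes were changed, up or down. In the 15611 genes of that step, edgeR recovered 78% of the 100 genes changed by a fold of 4 and 36% of the 100 changed by a fold of 2, with 9 false calls. DESeq2 1.42.0, run on 15787 genes of the same simulated comparison, recovered 85% and 59% with 69 false calls, and limma-voom recovered 76% and 35% with 10 false calls in 15611 genes.

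Alternatives fixed in advance were DESeq2, limma-voom, RLE and upper-quartile factors, no filter, a filter of CPM of at least 1 in 3 libraries, limma-trend on log2 FPKM with pseudocounts of 1 and 0.1, a replicate block, each library left out, and other thresholds. Corrections for gene length and GC content and covariates for oviduct and fat markers were added after seeing the data. Gene length was the effective length implied by the deposited counts and FPKM, and existed for 100% of tested genes. GC content came from the longest GENCODE M21 coding transcript of the same symbol and existed for 96.3%. Each library's deviation from the mean log2 CPM was fitted on the property by loess with a span of 0.3, and the fit was used as an offset. Pathway names from the deposited KEGG annotation were tested for the closing section by a one-sided Fisher's exact test against the 6283 tested genes that carry such a name. Figures were drawn with matplotlib 3.10.9.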

Results

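RNA from ovaries of balb/c-nude mice was profiled in 6 libraries of day 80, 3 of control mice and 3 of mice bearing tumors grown from MBA-MD-231 cells, the name the labels give to the injected line. Control libraries held between 18804610 and 19238900 estimated counts and tumor libraries between 18278614 and 18482073. Between 17999 and 18102 genes had a count above 0 in the control libraries and between 17891 and 18236 in the tumor libraries. The 10 most abundant genes took between 3.24% and 3.91% of the counts in every library. The comparison of tumor with control asks how the ovarian transcriptome differs in mice that carry a breast tumor, in a study whose title links tumors to oxidative stress and follicle loss.

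As lists, oocyte genes were higher and luteal, ovulatory, matrix and antioxidant genes were lower in ovaries of tumor-bearing mice than in control ovaries. No list kept its call with an estimated correlation among its genes, where the adjusted p of these lists lay between 0.442 and 0.565, and the antioxidant list lost its call after a correction for gene length (0.0614). The number of lists that passed did not set tumor apart from control. Of the 10 splits of the 6 libraries into 3 and 3, 7 gave at least as many lists, the real split included. Adipocyte markers also differed among the tumor libraries, with mean log2 CPM of 8.52, 5.72 and 7.68 in replicates 1, 2 and 3. Of 15787 genes tested with edgeR, 1217 changed at an adjusted p under 0.05, of which 600 were higher and 617 lower in tumor. Among them, 339 changed by at least 1 on the log2 scale, with 121 higher and 218 lower. The groups did not overlap in any of the 1217 changed genes; over all tested genes the groups did not overlap in 38.1%, where chance gives 10% for 3 libraries against 3. The smallest adjusted p was 0.00554, and 4893 genes had an unadjusted p under 0.05. The authors' deposited table listed 2833 genes with q under 0.05, 1422 above 0 and 1411 below, and 1207 of the 1217 genes were among them.

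Tumor replicate 1 stood apart from the other tumor libraries. On the first principal component of log2 CPM, which held 52.1% of the variance, it lay at -34.6, near control replicates 1 and 2 at -42.8 and -42.1, while control replicate 3 lay at -5.2 and tumor replicates 2 and 3 at 49.6 and 75.1. On the second, with 28.8%, it lay at -66.5 and the other libraries between -6.2 and 39.8. Its Spearman correlation across genes was 0.955, 0.969 and 0.953 with control replicates 1, 2 and 3, and 0.960 and 0.957 with tumor replicates 2 and 3. Genes are not independent replicates. The counts of changed genes rested on single libraries. Without control replicate 1 or tumor replicate 3 no gene passed edgeR's threshold, with 3137 and 3761 genes at an unadjusted p under 0.05, and 5 passed without control replicate 3 and 3 without tumor replicate 2, while 2274 passed without control replicate 2 and 2605 without tumor replicate 1; after a correction for gene length, added after seeing the data, 125 genes passed and 3303 had an unadjusted p under 0.05. The largest unadjusted p that passed was then 0.000387, against 0.00385 without the correction, so that a call could end while its fold change stayed. Of 74 changed genes named in the text, 45 lost their call in this way or by a smaller fold change; 33 of the 45 kept a log2 fold change within 1.5 times of the uncorrected one and 38 an unadjusted p under 0.05.

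Genes of the female germ line were higher in tumor ovaries as a list. Of the 21 growing oocyte genes, 11 rose, none fell and 10 did not pass the test; 18 rose when p-values were adjusted over the list alone. The list's median log2 fold change was 0.72, with an adjusted p of 1.08e-09 by camera and of 0.552 with an estimated correlation. Btg4, which acts in clearance of maternal mRNA, rose from 7.40 ± 1.06 to 17.1 ± 1.16 CPM (SD, n = 3 each), a log2 fold change of 1.21 ± 0.17 (SE) with an adjusted p of 0.0318. Nlrp14 rose from 54.6 ± 9.71 to 110.0 ± 14.4 CPM, and Npm2, an oocyte chromatin chaperone, and Ooep, a member of the subcortical maternal complex, rose by log2 fold changes of 0.72 and 0.68. The oocyte growth factors Gdf9 and Bmp15 also rose, by 0.76 ± 0.15 and 0.99 ± 0.17 (SE), with adjusted p of 0.0396 and 0.0382. Zp3, a zona pellucida gene, had a log2 fold change of 0.34 with an adjusted p of 0.165, which was 0.60 after the length correction and 0.04 with the mean of adipocyte markers as a covariate. After the length correction Btg4, Nlrp14, Npm2 and Ooep stayed under 0.05, while Gdf9 had 0.95 ± 0.17 (SE) with an adjusted p of 0.0573 and Bmp15 1.05 ± 0.20 (SE) with one of 0.0649.

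Early oocyte genes lay in the same direction. Of 11 tested genes of primordial and early oocytes, Foxo3 and Dazl rose and 9 did not pass the test, with 8 higher after adjustment over the list alone. The median log2 fold change was 0.90, with an adjusted p of 1.15e-05 by camera and of 0.442 with an estimated correlation. Dazl, a germ cell RNA-binding protein gene, rose from 1.63 ± 0.19 to 4.14 ± 0.55 CPM (SD, n = 3 each), with an adjusted p of 0.0385. Ddx4, the germ cell helicase also called vasa, was measured at 5.34 ± 1.80 CPM in control and 11.9 ± 1.32 CPM in tumor with an adjusted p of 0.0536, and Sycp3 had a log2 fold change of 1.68 with an adjusted p of 0.0533. With the mean of oviduct markers as a covariate both passed, with adjusted p of 0.0395 and 0.0295, while with that of adipocyte markers Sycp3 had 0.65. Figla, measured near 1 CPM, had a log2 fold change of 0.52 (adjusted p of 0.331), which was 0.34 without control replicate 1 and 0.86 after the length correction. Both calls ended after the length correction: Foxo3 moved from 0.55 ± 0.09 to 0.36 ± 0.12 (SE), with an adjusted p of 0.160, and Dazl from 1.34 ± 0.24 to 1.40 ± 0.25, with one of 0.0573. On log2 FPKM plus 1 Dazl had 0.67.

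**Figure D1:**
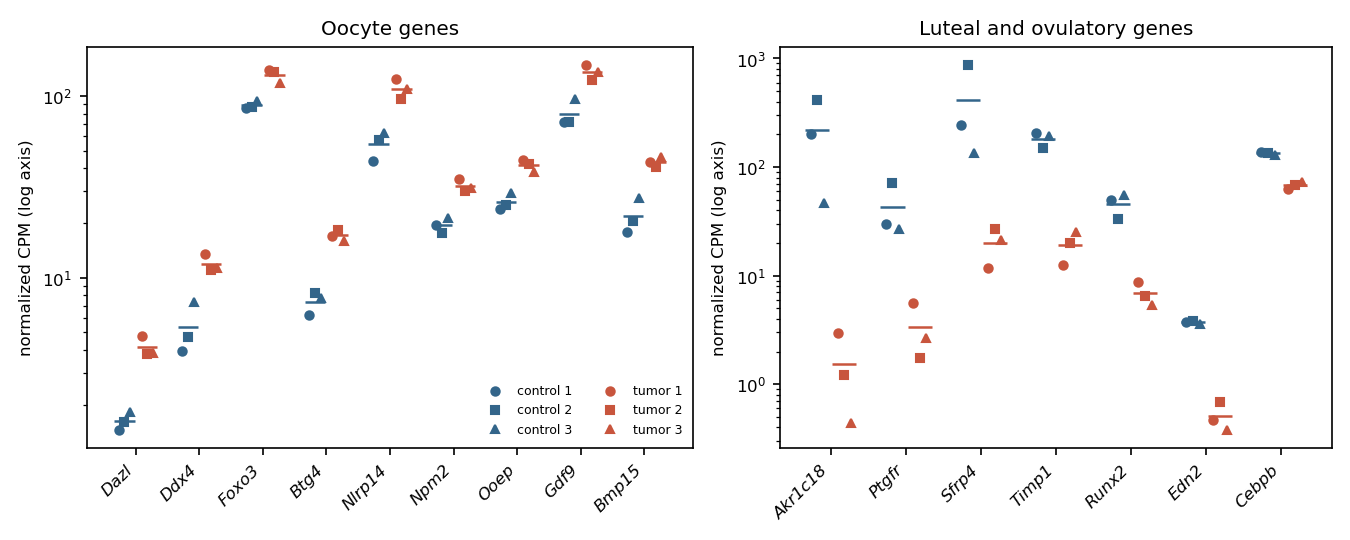
Normalized CPM on a log axis in each library for 9 oocyte genes (left) and 7 luteal and ovulatory genes (right), with symbols for replicates and bars for group means of 3. Gdf9 averages 80.2 CPM in control and 135.5 CPM in tumor, while Timp1 averages 182.6 CPM in control and 19.2 CPM in tumor.

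Somatic follicle genes moved less uniformly. Of 17 granulosa cell genes, only Esr2, the gene of estrogen receptor beta, rose in edgeR's test, from 61.4 ± 6.53 to 133.0 ± 12.4 CPM (SD, n = 3 each) with an adjusted p of 0.0248; 2 rose after adjustment over the list alone. The list had a median log2 fold change of 0.47 and a camera adjusted p of 0.0518. That adjusted p was 0.0532, 0.0296 and 0.0230 after the length correction, the GC correction and both, and 0.843 with an estimated correlation. The gap junction gene Gja1 had a log2 fold change of 0.88 and the kit ligand gene Kitl one of 0.62, with adjusted p of 0.0572 and 0.0796. Amh, the anti-Müllerian hormone gene of growing follicles, was measured at 260.4 ± 68.2 CPM in control and 214.7 ± 37.4 CPM in tumor, with an adjusted p of 0.446; its log2 fold change of -0.28 turned to 0.17 after a correction for GC content, and was -0.08 without control replicate 3 and -0.43 without control replicate 2 or tumor replicate 3. Of 12 theca genes, the hedgehog targets Hhip and Ptch1 rose by log2 fold changes of 1.18 and 0.78 and 10 did not pass, with a camera adjusted p of 0.720 for the list; adjusted over the list alone, 2 rose and 1 fell. Esr2 stayed under 0.05 after the length correction, while Hhip, with 0.78 on log2 FPKM plus 1, then had 0.96 ± 0.22 (SE) with an adjusted p of 0.0878 and Ptch1 0.58 ± 0.19 with one of 0.155. Cyp17a1, the theca enzyme of androgen synthesis, had a log2 fold change of 0.51 with an adjusted p of 0.899, and its sign turned with control replicate 1 (-0.08), control replicate 3 (-0.07) or tumor replicate 3 (-0.20) left out.

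Luteal and ovulatory genes were lower in tumor ovaries as lists. The labels give no stage of the estrous cycle at collection, and a difference in stage between the groups was not tested. Of 13 luteal genes, 4 fell, none rose and 9 did not pass; adjusted over the list alone, 4 fell. The median log2 fold change was -1.09, with an adjusted p of 0.000777 by camera and of 0.551 with an estimated correlation. Akr1c18, which inactivates progesterone, averaged 221.5 CPM in control and 1.54 CPM in tumor, with 200.1, 417.4 and 47.0 CPM in the control libraries and 2.96, 1.23 and 0.436 CPM in the tumor libraries. The prostaglandin F receptor gene Ptgfr and Sfrp4, a secreted Wnt modulator, had log2 fold changes of -3.68 ± 0.61 and -4.38 ± 0.83 (SE) with adjusted p of 0.0385 and 0.0412. Timp1, a metalloproteinase inhibitor, fell from 182.6 ± 28.4 to 19.2 ± 6.35 CPM (SD, n = 3 each), with an adjusted p of 0.0206. The steroidogenic genes Cyp11a1 and Star did not pass, with log2 fold changes of -1.93 ± 0.66 and -1.41 ± 0.74 (SE) and adjusted p of 0.112 and 0.25, but with the mean of oviduct markers as a covariate they had -3.19 and -2.91 with adjusted p of 0.0151 and 0.0140, and with that of adipocyte markers -0.94 and -0.61 with adjusted p of 0.632 and 0.831. Without tumor replicate 1 Star had -0.92, and without tumor replicate 3 it had -2.12. After the length correction Timp1 stayed under 0.05, and the calls of Akr1c18, Ptgfr and Sfrp4 ended with falls about as large, of -6.91 ± 1.12, -3.74 ± 0.57 and -4.15 ± 0.87 (SE) and adjusted p of 0.0649, 0.0572 and 0.0937. On the log2 CPM scale the list median was -1.07, and it was -1.67 with that covariate and -0.63 with the mean of adipocyte markers instead, with camera adjusted p of 8.45e-06 and 0.0124.

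Of 12 tested ovulatory response genes, 3 fell, none rose and 9 did not pass; 7 fell after adjustment over the list alone. The median log2 fold change was -1.32, with a camera adjusted p of 0.000777 and one of 0.442 with an estimated correlation. Runx2, a transcription factor of the periovulatory follicle, fell from 45.8 ± 11.2 to 6.86 ± 1.76 CPM (SD, n = 3 each). Edn2, the endothelin gene of ovulation, and Cebpb, a transcription factor induced by luteinizing hormone, had log2 fold changes of -2.83 and -0.97 with adjusted p of 0.0259 and 0.0206. Runx2 and Edn2 stayed under 0.05 after the length and the GC correction, but Cebpb had -0.73 with an adjusted p of 0.0649 after the first and -0.49 with one of 0.104 after the second. With limma-trend on log2 FPKM plus 1 Edn2 had -1.38 and the list median was -0.48, with a camera adjusted p of 0.000232.

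Extracellular matrix genes were also lower as a list. Of 17 tested genes of matrix and myofibroblasts, 7 fell, none rose and 10 did not pass; 11 fell after adjustment over the list alone. The median log2 fold change was -0.99, with a camera adjusted p of 1.14e-05 and one of 0.551 with an estimated correlation. Col1a1, a chain of type I collagen, fell from 1023 ± 151.6 to 450.7 ± 127.2 CPM (SD, n = 3 each), and Col5a2 and Sparc had log2 fold changes of -1.49 and -1.20. Timp1 belongs to both this list and the luteal list, and it stayed under 0.05 after the length correction, where Col1a1, Col5a2 and Sparc had log2 fold changes of -1.33 ± 0.27, -1.68 ± 0.28 and -1.02 ± 0.27 (SE), against -1.18 ± 0.23, -1.49 ± 0.24 and -1.20 ± 0.23 without it, and adjusted p of 0.0717, 0.0572 and 0.112.

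Antioxidant genes were lower in tumor ovaries as a list. Of 25 antioxidant and NRF2 target genes, 8 fell, none rose and 17 did not pass; adjusted over the list alone, 11 fell and 1 rose. The median log2 fold change was -0.30, with an adjusted p of 0.00289 by camera and of 0.565 with an estimated correlation. Hmox1, the inducible heme oxygenase gene, fell from 108.2 ± 26.4 to 35.0 ± 3.80 CPM (SD, n = 3 each), a log2 fold change of -1.63 ± 0.19 (SE) with an adjusted p of 0.0277. The glutathione peroxidase genes Gpx1 and Gpx3 and the extracellular superoxide dismutase gene Sod3 had log2 fold changes of -1.10, -1.39 and -1.06. Nqo1, an NRF2 target, fell from 14.2 ± 2.51 to 6.85 ± 0.273 CPM. Sod2, the mitochondrial superoxide dismutase gene, stood at 94.8 ± 5.45 CPM in control and 94.6 ± 7.78 CPM in tumor, and the catalase gene Cat had a log2 fold change of 0.92 ± 0.48 (SE) with an adjusted p of 0.252. Cat was measured at 470.5, 115.8 and 225.6 CPM in tumor replicates 1, 2 and 3, where the mean log2 CPM of adipocyte markers was 8.52, 5.72 and 7.68, and its log2 fold change was 0.26 without tumor replicate 1 and -0.56 with that mean as a covariate. The list's median was -0.10 after the length correction and -0.15 after the GC correction. Its camera adjusted p was 0.0614 after the length correction and lay between 0.000114 and 0.0614 over the alternatives with the preset correlation. Hmox1 and Gpx3 stayed under 0.05 after the length correction, while Gpx1, Sod3 and Nqo1 had -0.79 ± 0.14, -0.87 ± 0.20 and -0.82 ± 0.21 (SE), against -1.10 ± 0.15, -1.06 ± 0.15 and -1.05 ± 0.19 without it, and adjusted p of 0.0649, 0.0851 and 0.106.

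**Figure D2:**
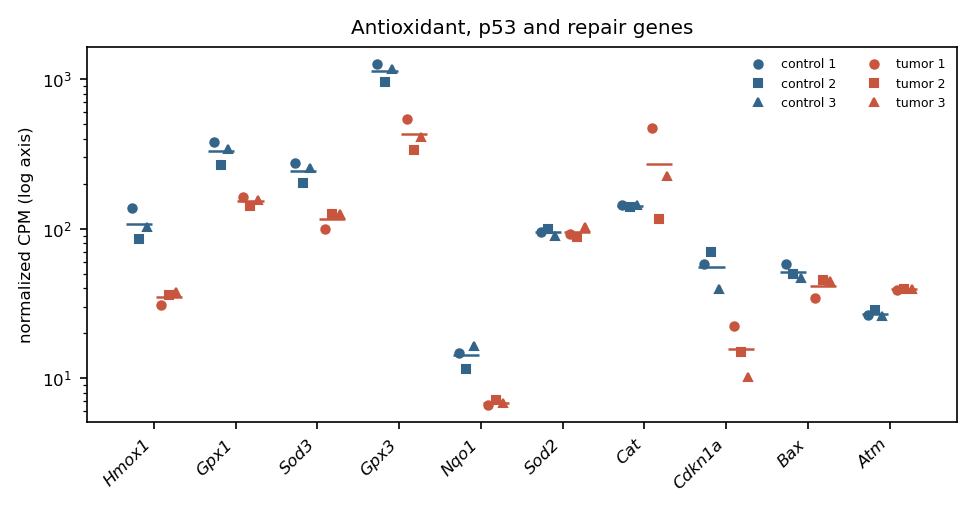
Normalized CPM on a log axis in each library for 7 antioxidant genes, 2 p53 targets and the repair kinase gene Atm, with symbols for replicates and bars for group means of 3. Hmox1 averages 108.2 CPM in control and 35.0 CPM in tumor, while Sod2 averages 94.8 CPM and 94.6 CPM.

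Oxidative phosphorylation genes were slightly lower as a list. Of 36 subunit genes, 5 fell, none rose and 31 did not pass, with 19 lower after adjustment over the list alone. Ndufa1 of complex I and Sdhb of complex II had log2 fold changes of -0.83 and -0.55, and Uqcrb and Cox6a1 had -0.50 and -0.68. The list's median of -0.31 had an adjusted p of 7.71e-07 by camera, of 0.772 with an estimated correlation and of 0.0729 with fry. After the length correction its median was 0.01, with a camera adjusted p of 0.498, the highest with the preset correlation, where the lowest was 6.65e-09. Ndufa1, Sdhb, Uqcrb and Cox6a1 then had -0.39, -0.24, -0.08 and -0.25, with adjusted p of 0.216, 0.482, 0.781 and 0.547.

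Genes of DNA repair and growth signaling were slightly higher, with list medians of 0.32 and 0.26. Of 19 tested double-strand break repair genes, 2 rose, none fell and 17 did not pass, and 2 rose after adjustment over the list alone. Atm, the kinase that senses double-strand breaks, and Rad50 rose by log2 fold changes of 0.53 ± 0.09 and 0.34 ± 0.08 (SE), while Brca1 had 0.41 with an adjusted p of 0.407, and 0.19 without control replicate 2, 0.65 without control replicate 3 and 0.23 without tumor replicate 3. The repair list had a camera adjusted p of 0.00916, one of 0.551 with an estimated correlation and one of 0.146 after the length correction, within a range of 0.00245 to 0.394 over the alternatives with the preset correlation. It lost its call without tumor replicate 3 (0.0510), after the GC correction (0.158), with the oviduct mean as a covariate (0.179) and with fry (0.0929). Corrected for length, Atm had 0.27 with an adjusted p of 0.262 and Rad50 0.24 with one of 0.244. Of 21 genes of the PI3K, AKT, mTOR and FOXO3 pathway, 4 rose, none fell and 17 did not pass, with 8 higher after adjustment over the list alone. Foxo1, Rictor, Pik3ca and Foxo3 rose by log2 fold changes of 0.95, 0.55, 0.46 and 0.55. Mtor had 0.29 with an adjusted p of 0.125, and it had 0.09 after the length correction and 0.48 after the GC correction. The pathway list's camera adjusted p was 0.00916, and its adjusted p was 0.552 with an estimated correlation and 0.0913 after the length correction, within a range of 0.00269 to 0.0913 over the alternatives with the preset correlation. It also lost its call with the oviduct mean as a covariate (0.0593) and after both corrections (0.0562). After the length correction alone Foxo1, Rictor, Pik3ca and Foxo3 had 0.84, 0.32, 0.27 and 0.36, with adjusted p of 0.115, 0.157, 0.261 and 0.160.

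Of 20 genes of the apoptosis machinery, 4 fell and 1 rose, and 15 did not pass; adjusted over the list alone, 6 fell and 1 rose. The lower genes included the death-promoting Bmf and Bad, with log2 fold changes of -0.82 and -0.60, and Tnfrsf1a, a receptor of tumor necrosis factor, with -0.58. The inhibitor of apoptosis gene Xiap rose by 0.38, which was 0.20 after the length correction, 0.13 after the GC correction and 0.00 after both together. After the length correction Bmf, Bad and Tnfrsf1a had -0.90, -0.30 and -0.40, with adjusted p of 0.0569, 0.170 and 0.235, and the adjusted p of Xiap was 0.312. Bax had -0.31 with an adjusted p of 0.195, and 0.05 after the length correction, -0.20 without control replicate 1 and -0.19 without tumor replicate 1. Of 20 p53 targets only Cdkn1a, a cell cycle inhibitor gene, changed in edgeR's test, falling from 55.8 ± 15.0 to 15.8 ± 6.04 CPM (SD, n = 3 each), and 2 fell after adjustment over the list alone. After the length correction its log2 fold change was -1.65 ± 0.27, against -1.82 ± 0.34 (SE) without it, and its adjusted p was 0.0542. The camera adjusted p was 0.324 for the apoptosis list and 0.897 for the p53 list.

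The named genes with the largest falls were Wnt10b, Akr1c18, Dcpp1, Bhmt, Cldn18, Plekhg4, Ptprn, Sstr1, Mmel1 and Wnt10a. Wnt10b (NCBI gene 22410, chromosome 15, 98770712 to 98778206 on GRCm38.p6), a secreted Wnt ligand, averaged 55.8 ± 29.5 CPM in control and 0.371 ± 0.206 CPM in tumor (SD, n = 3 each), a log2 fold change of -7.20 ± 0.60 (SE) with an adjusted p of 0.0206. The others had log2 fold changes between -7.15 and -5.01 with adjusted p between 0.0248 and 0.0474. Akr1c18, Dcpp1, Bhmt and Wnt10a no longer passed after the length correction, with falls about as large, of -6.91, -5.99, -5.61 and -4.82, and adjusted p of 0.0649, 0.0949, 0.0882 and 0.0871. Their calls also ended with limma-voom, with adjusted p of 0.0697, 0.121, 0.146 and 0.0644. With limma-trend on log2 FPKM plus 1 the values of these genes shrank by over 1.5 times except that of Akr1c18, to -4.08 for Wnt10b, -2.16 for Bhmt, -2.07 for Mmel1, -1.44 for Wnt10a and -1.17 for Cldn18, and the calls of Dcpp1, Bhmt and Wnt10a ended. Bhmt, Dcpp1 and Wnt10a varied widely among the control libraries, with SDs of 8.63, 11.4 and 2.69 CPM around means of 11.1, 13.9 and 4.22 CPM, and the estimated counts of Dcpp1 and Akr1c18 may share reads with close paralogs.

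The named genes with the largest rises were Gpnmb, Itih4, Atp1a4, Cbln1, H2ac24, Zbed6, Hlf, Zbtb20, Zfp966 and Per3, with log2 fold changes between 1.81 and 2.85. Of these, Gpnmb, Cbln1, Zbed6 and Zbtb20 no longer passed after the length correction, with rises about as large, of 2.82, 2.78, 1.87 and 1.67, and adjusted p of 0.0961, 0.0649, 0.0759 and 0.0639. The calls of Gpnmb, Cbln1 and Zbed6 also ended with limma-voom, and on log2 FPKM plus 1 Itih4, Atp1a4, Cbln1 and Zbed6 had 1.38, 0.88, 0.98 and 0.95, the last 2 no longer passing. With the mean of adipocyte markers as a covariate, where no gene passed, Itih4 had 1.73 and Zbed6 0.86. Hlf (NCBI gene 217082, chromosome 11, 90333910 to 90390917), a transcription factor of the circadian output pathway, rose from 10.3 ± 2.05 to 40.1 ± 8.65 CPM (SD, n = 3 each), a log2 fold change of 1.96 ± 0.21 (SE) with an adjusted p of 0.0265. The clock gene Per3 rose from a mean of 22.8 CPM to one of 80.2 CPM, a log2 fold change of 1.81 ± 0.23 (SE) with an adjusted p of 0.0301, and no time of day is given in the sources used here. Gpnmb, a glycoprotein gene of lysosome-rich cells, rose from 20.4 ± 8.68 to 146.8 ± 83.4 CPM with an adjusted p of 0.0459. The counts of Zbed6, which lies inside Zc3h11a, of Zfp966, which overlaps 13 other genes of the table, and of the histone gene H2ac24 are uncertain because reads could be shared.

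**Figure D3:**
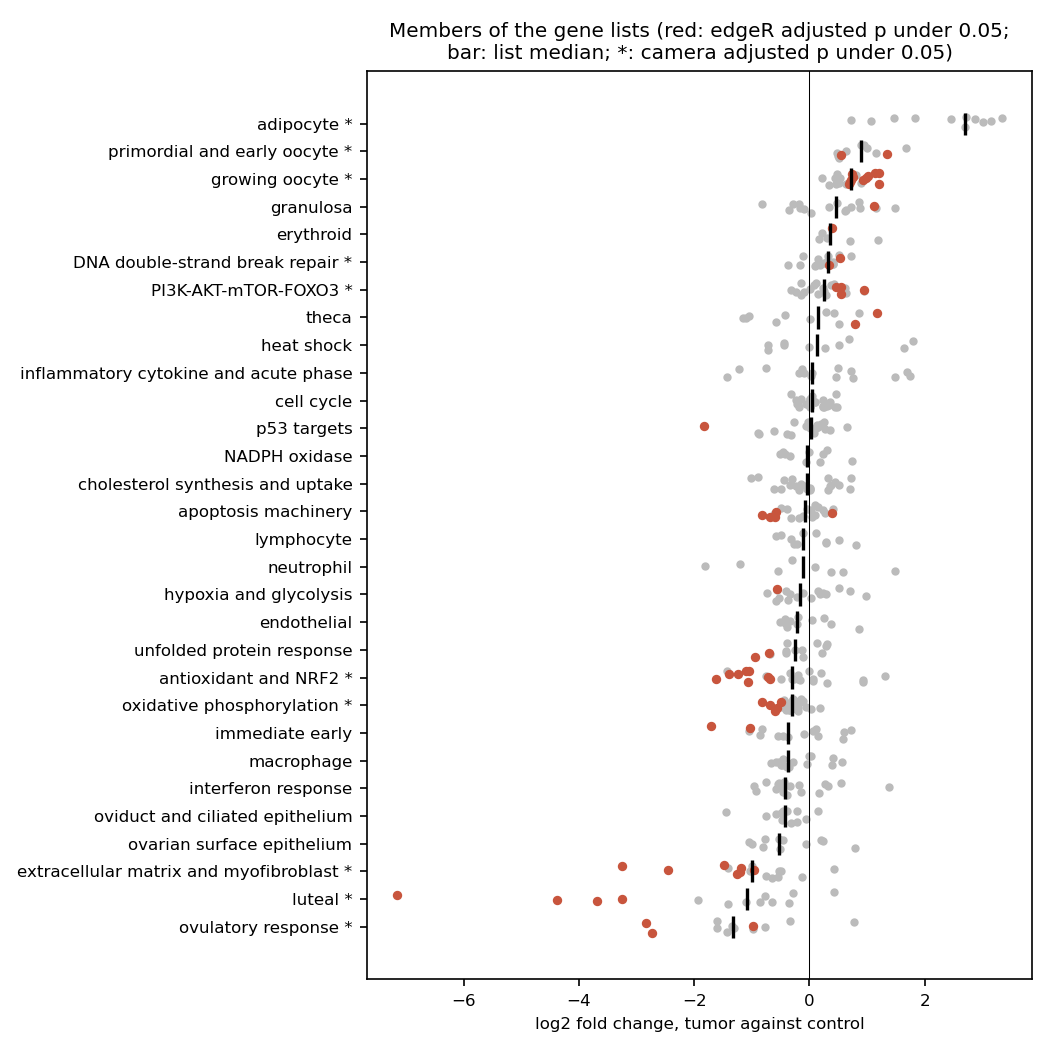
Log2 fold change of each tested member (points) of 30 gene lists in tumor against control, with list medians as bars, red points at an edgeR adjusted p under 0.05 and asterisks at a camera adjusted p under 0.05. The growing oocyte list has its median at 0.72 and the luteal list at -1.09, and no list keeps its asterisk with an estimated correlation.

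Markers of neighboring tissues differed between libraries. Adipocyte genes had a mean log2 CPM of 5.24, 5.67 and 5.36 in the control libraries and 8.52, 5.72 and 7.68 in tumor replicates 1, 2 and 3. No adipocyte gene passed edgeR's test over all genes and 10 of 11 were higher after adjustment over the list alone, with a median log2 fold change of 2.70 and a camera adjusted p of 0.000777, or 0.826 with an estimated correlation and 0.212 with fry. On the log2 CPM scale the list median was 2.16, and 1.43 without tumor replicate 1. Adipoq, the adiponectin gene, was measured at 529.3, 54.8 and 227.9 CPM in the tumor libraries and at 36.4 to 48.2 CPM in the controls. Oviduct and ciliated epithelium genes had means of 5.69, 6.18 and 4.51 in control and of 6.56, 3.25 and 1.73 in tumor, with a camera adjusted p of 0.107. That adjusted p was 0.0297, 0.0166 and 0.0245 after the length correction, the GC correction and both, and 0.929 with an estimated correlation. Ovgp1, the oviduct glycoprotein gene, was measured at 1821, 1627 and 308.9 CPM in control and at 1290, 70.1 and 16.4 CPM in tumor. With the adipocyte mean as a covariate, an alternative chosen after seeing the data, no gene passed edgeR's threshold and 2417 had an unadjusted p under 0.05; with the oviduct mean, 2533 genes passed.

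Fold changes also followed gene length. Across genes the Spearman correlation of log2 fold change with length was 0.37 and with GC content -0.35; genes are not independent replicates. The 1582 shortest genes had a median log2 fold change of -0.32, with 12 genes higher and 166 lower, and the 1579 longest had 0.30, with 214 higher and 19 lower. The 125 genes that passed after the length correction were 57 higher and 68 lower, and all of them were among the 1217.

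**Figure D4:**
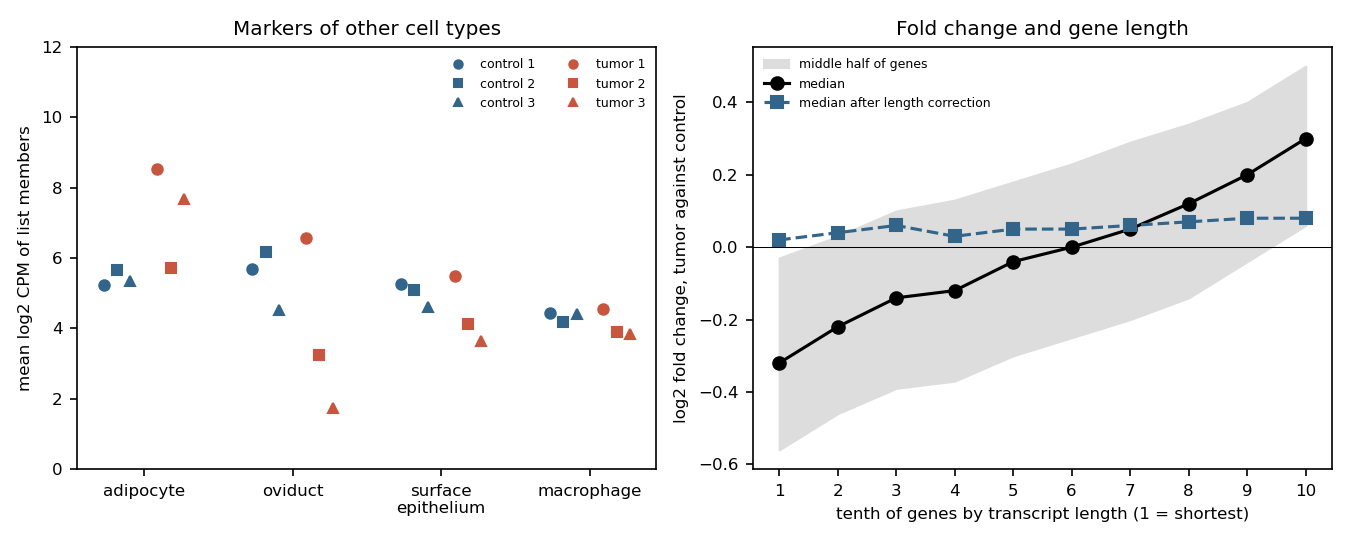
Mean log2 CPM of the members of 4 lists of other cell types in each library (left), and the median log2 fold change in 10 bins of genes by length before and after correction, with the interquartile range shaded (right). The adipocyte mean reaches 8.52 in tumor replicate 1 against 5.24 to 5.67 in the controls, and the median fold change runs from -0.32 in the bin of the shortest genes to 0.30 in that of the longest.

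The other lists did not pass camera's threshold in the main test. Besides the granulosa, theca, apoptosis and p53 lists, single members passed edgeR's test in 4 of them: Nr4a1 and Junb of the immediate early list, with log2 fold changes of -1.71 and -1.03, Eno1 of hypoxia and glycolysis with -0.56, Sdf2l1 and Calr of the unfolded protein response with -0.95 and -0.71, and Bpgm of the erythroid list with 0.40. After the length correction only Nr4a1 of these stayed under 0.05, with -0.35 for Eno1 and 0.64 for Bpgm, and Junb had -0.66 after the GC correction. Inflammatory and interferon lists had no changed member and medians of 0.05 and -0.42. Of their tested members, 9 inflammatory and 5 interferon genes lay above 0, and 6 and 13 below. The members with the smallest p of these lists, Tnf and Rsad2, had log2 fold changes of 1.74 and 1.38 with adjusted p of 0.107 and 0.0895. On log2 FPKM plus 1 they had 0.50 and 0.88, and Tnf passed with the oviduct mean as a covariate (0.0343). The neutrophil, macrophage and lymphocyte lists had medians of -0.11, -0.37 and -0.11, the endothelial list -0.21 and the surface epithelium list -0.52. Surface epithelium genes had means of 5.26, 5.10 and 4.60 log2 CPM in control and of 5.49, 4.13 and 3.63 in tumor. Cell cycle, cholesterol, NADPH oxidase and heat shock lists had medians of 0.04, -0.04, -0.04 and 0.13. The test's direction differed in sign from the median for the NADPH oxidase, lymphocyte and p53 lists, and the theca list had a median of 0.15 and a mean of -0.02. Skeletal muscle had 4 tested genes and was not tested as a list.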

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

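The corrections for gene length and GC content and the oviduct and fat covariates were chosen after seeing the data. Counts of changed genes stayed within 1.5 times the 1217 (600 higher, 617 lower) with limma-voom, RLE and upper-quartile factors, either filter and both FPKM pseudocounts, from 957 to 1433. DESeq2 gave 3029 (1526 higher, 1503 lower) and an adjusted p under 0.1 gave 3256 (1652 and 1604); a log2 fold change of at least 1 gave 339 (121 and 218). Length correction gave 125 (57 and 68), GC correction 168 (85 and 83) and both 82 (34 and 48). The oviduct covariate gave 2533 (1054 and 1479) and the fat covariate 0 (0 and 0), with 2417 at an unadjusted p under 0.05. Leaving out 1 library gave 0 to 2605 changed, 0 to 1188 higher, 0 to 1534 lower and 10 to 15 lists: 0 genes without control replicate 1 (3137 at an unadjusted p under 0.05) or tumor replicate 3 (3761), 5 without control replicate 3, 3 without tumor replicate 2, 2274 without control replicate 2 and 2605 without tumor replicate 1, and 15 lists without control replicate 3 or tumor replicate 1. Of the 10 lists, 0 passed with an estimated correlation, where 2 had an unadjusted p under 0.05, and 7 with fry; 17 lists passed with the fat covariate. The cause was not tested. Fewer libraries or residual degrees of freedom enter the fits with a library left out or a covariate. That alone does not account for the counts, since leaving out 1 library gave 0 to 2605 genes and the covariates gave 0 and 2533. At this depth and number of libraries, 36% of simulated changes of a fold of 2 were recovered.

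With a replicate block edgeR called 0 genes (0 higher, 0 lower; 4233 at an unadjusted p under 0.05) and 12 lists passed. The labels do not say whether the numbers pair the samples. Deviations from the group means correlated at 0.24, -0.21 and 0.53 for numbers 1, 2 and 3. Of the 6 libraries, 3 correlated best with their own number, and so few libraries cannot decide whether the samples are paired.

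Of 74 named genes with adjusted p under 0.05, 29 passed after the length correction, 32 after the GC correction and 0 with the fat covariate or with control replicate 1 or tumor replicate 3 left out, while 74 passed with DESeq2; 2 passed without control replicate 3, 1 without tumor replicate 2, 66 without control replicate 2 and 74 without tumor replicate 1. Signs turned for Xiap (0.00 with both corrections) and, among genes and lists below, the adipocyte list (-0.08, fat covariate), Cat (-0.56, fat covariate), Amh (0.17 with GC and 0.19 with both corrections) and Bax (0.05, 0.09 and 0.24 with length, GC and both). The fat covariate is the mean of the adipocyte list itself, so it removes that list's change by construction. Sod2 was 0.01 with DESeq2, RLE and upper-quartile factors, 0.06 on both FPKM scales and -0.07 to 0.08 with 1 library left out. Cyp17a1 was -2.63 with the oviduct covariate and -0.20 to 6.17 with 1 library left out. With that covariate Oas1d was -1.30 and Oas1h -1.07.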

Other observations

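The tests in this part were chosen after the result was seen, except the comparison with lists matched on GC content and the counts over other splits of the samples. Lysosomal genes were lower in tumor ovaries as a set, 1 of 11 lower and 11 higher pathways past an adjusted p of 0.05. Of 116 tested genes that the deposited KEGG annotation places in the lysosome, 17 fell against 5.5 expected, an odds ratio of 3.58 with an adjusted p of 0.00407 over 652 one-sided Fisher's exact tests in 326 pathways; among the others were oxidative phosphorylation, lower with 0.000202, and pluripotency and FoxO signaling, higher with 0.00116 and 0.00407 but with camera adjusted p of 0.114 and 0.158. The lysosome term's median log2 fold change was -0.29, and camera, run on all 326 terms, gave an adjusted p of 6.19e-05, of 0.000295 after the length correction and of 0.981 with an estimated correlation, where none of these pathways passed; after the length correction 4 of the 11 lower and 0 of the 11 higher ones did. Gm2a, the activator of ganglioside breakdown, fell from 623.8 ± 16.4 to 170.8 ± 8.69 CPM (SD, n = 3 each) with an edgeR adjusted p of 0.00554, the smallest of all genes. The protease gene Lgmn fell from 290.6 ± 40.0 to 80.5 ± 4.0 CPM, and both genes stayed under 0.05 after the length correction. Ctsb, Psap and the proton pump subunit gene Atp6v0e2 had log2 fold changes of -0.83, -0.75 and -1.16, and their calls ended after the length correction, with -0.63 ± 0.14, -0.65 ± 0.18 and -0.97 ± 0.18 against SEs of 0.10, 0.14 and 0.21 before. These 5 genes were chosen after their values were seen.

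Several genes split the libraries in a way that did not follow the groups. Cyp17a1, the theca enzyme of androgen synthesis, was measured at 14.3, 2669 and 22.1 CPM in control replicates 1, 2 and 3 and at 37.5, 1533 and 2273 CPM in tumor replicates 1, 2 and 3. Oas1d, a member of the growing oocyte list, was at 0 CPM in control replicates 1 and 3, 16.7 CPM in control replicate 2, and 0.104, 14.0 and 15.3 CPM in the tumor libraries. Its neighbor Oas1h showed 0 CPM in the same control libraries and in tumor replicate 1, and 4.58 to 6.05 CPM in the other 3 libraries. A count of 0 allows up to 0.156 CPM in control replicate 1, 0.158 in control replicate 3 and 0.164 in tumor replicate 1. These limits were computed without TMM factors, unlike the CPM levels given here. Oas1d and Oas1h belong to a gene family, so their estimated counts are uncertain. Akr1b7 was measured at 78.4, 1.23 and 108.2 CPM in control and at 0.0520, 6.82 and 3.98 CPM in tumor. Akr1b7, Oas1d and Oas1h were singled out after their values were seen.

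Oocyte genes were higher in tumor ovaries, with a median log2 fold change of 0.73 over 32 genes of both oocyte lists. A length trend as the whole cause is argued against in these libraries, since the median was 0.95 ± 0.06 (bootstrap SE) after the length correction. The growing oocyte genes are short, with a median length of 1440 bases, and the trend lowered short genes. A higher median of that list after the correction thus followed from their lengths. The bootstrap SEs here resample genes, which are not independent, and do not measure the spread between libraries. Less oviduct RNA in the tumor libraries as the whole cause is argued against as well, since the median was 0.70 ± 0.07 with the mean of oviduct markers as a covariate. A smaller share of luteal RNA remains open: the oocyte median lay 0.35 ± 0.23 above that of 28 granulosa and theca genes, and this difference is too close to its error to decide. A greater number or share of oocytes per ovary, which may come with tumor bearing, stays untested as a hypothesis, because follicle counts were not used here.

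Oxidative phosphorylation and antioxidant genes were lower in tumor ovaries, and both lists hold mostly short genes. The oxidative phosphorylation median of -0.31 lay at percentile 33.4 of 10000 random lists matched on length, whose own median was -0.28, so a length trend is a candidate explanation for that list as a whole. The antioxidant median of -0.30 lay at percentile 6.53 of lists matched on length. Their range of -0.34 to 0.05 leaves a length trend open for part or all of the change. The medians lay at percentiles 0.06 and 0.18 of lists matched on GC content, and after the GC correction they were -0.24 and -0.15. The random lists drew genes independently, whereas the genes of the real lists were correlated, with estimates of 0.549 and 0.144. The percentiles are therefore too extreme, and they do not decide on a trend with GC content alone. The trend itself, with slopes per doubling of length of -0.148, -0.028 and -0.077 in control and 0.063, 0.098 and 0.091 in tumor libraries, may be technical or biological. A simulated trend of the same size, with no other change, called 3 genes. That simulation does not tell how many calls the trend adds in data where other genes also change.

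Clock genes formed 2 opposed sets. All 10 of Per1, Per2, Per3, Nr1d1, Nr1d2, Dbp, Tef, Hlf, Ciart and Bhlhe41 had positive log2 fold changes and 5 rose, Tef and Nr1d2 by 1.26 and 1.21, while 3 of 4 genes of the opposite phase were below 0, Npas2 with -2.08 (adjusted p of 0.0277, and -1.31 on log2 FPKM plus 1) and Arntl with -1.45 (adjusted p of 0.0543, and 0.00439 with the oviduct covariate). The mean log2 CPM of the first set minus that of the second was -0.04, 0.04 and 0.00 in control and 2.78, 2.07 and 1.5 in tumor libraries, a difference of 2.12 for which no p is given, since most of the genes were chosen after their values were seen. After the length correction the difference was 2.09 ± 0.39 (SE), so the correction took away little of it in these genes. Because the genes were picked by their values, the size of the difference and its SE are not a test of a cause. Collection of the groups at different times of day cannot be told apart from an effect of the tumor on the clock, because the labels give no time, and both remain hypotheses. Hlf and Per3 were named by the fixed rule, which takes the largest rises, so they too were selected by their values. All the other genes of these 2 sets were chosen after their values were seen.

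The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 1217 changed genes, 600 higher and 617 lower, and it was the only 1 of the 10 splits with a count as large in each case; the highest count of any other split was 21. The number of gene lists did not set the real split apart. At least its 10 lists passed in 7 of the 10 splits, the real one included, and the highest other split gave 17. That split set control replicates 1 and 2 and tumor replicate 1 apart from the rest, and these 3 libraries had the highest means of oviduct markers, 5.69, 6.18 and 6.56 log2 CPM.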
